A study of Mus musculus with 40 samples.

How the data were processed

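The series holds RNA sequencing of 4T1 cells, a mouse mammary carcinoma line derived from a BALB/c tumour, cultured alone or with T cells from C57Bl6 spleens. Wells were uncoated tissue culture polystyrene or the same plastic coated with collagen I, collagen IV, fibronectin or vitronectin at 250 µg/ml. Per the labels, 10000 carcinoma cells and 80000 T cells were seeded per cm2, both arms received interleukin 2 at 30 U/mL, and co-culture lasted 24 h. Free cells were pelleted and pooled with the trypsinised cells before RNA extraction, so each co-culture library holds RNA of carcinoma cells and T cells in 1 mixture. Libraries were made from total RNA with a poly(A) selection kit and read as single ends of 75 bases. The 40 libraries fall into 10 groups, 22 libraries of 4T1 alone and 18 co-cultures, and come from 5 experiments.

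The submitters' processing notes name STAR 2.6, featureCounts (version not given), edgeR 3.31.7 and the mouse build mm10, without options, order or the annotation used. The deposited values are an expression signal per gene and library. They behave as read counts divided by a scaled library size in M (mega-reads), and are called per M here. Columns sum to between 956225 and 1037118, so a scaling factor beyond the column total had been applied. Dividing each column by the value of 1 read gave whole reads for 100% of the values, within 0.01 of a whole number, with a largest distance of 0.0014. The recovered depth was 18.95 to 239.13 M assigned reads per library, with a median of 34.6 M and a second highest of 47.73 M. A count of 0 allows up to 3 reads, which is 0.0124 to 0.158 per M depending on the library. Reads carry no molecular identifiers, so these limits cover counting error only. The 10 highest genes took 4.10% to 5.42% of the signal of a library.

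The table had 21349 lines. Cd3d stood on 2 lines with identical values and was kept once. Ldha had a cell that held no number in 1 library and was left out, and 19 symbols had turned into dates and belong to no list. Of the 21347 genes kept, 14701 reached 1 per M in at least 3 libraries and were tested. No mitochondrially encoded and no Y-linked gene of the lists was in the table, so these could not serve as signs of RNA quality or of sample identity. No pair of libraries within a group was a copy of another: the chi-square per degree of freedom over recovered reads was 7.03 to 744.7 in 62 pairs.

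Values were analysed as log2(value + 1) with limma 3.58.1 in R 4.3.3. A model of the 10 group means was fitted to all 40 libraries (30 residual degrees of freedom) with an intensity trend in the prior variance. It holds no term for the experiment, so differences between experiments stay in its residual spread. A result of 0 genes passing therefore does not show that no gene differed. P values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. At an unadjusted p under 0.05, chance alone would give a share of 0.05 of the genes tested. Differences are log2 differences ± SE on this scale, and adding 1 pulls in those of genes near 0. The comparisons were T cells added against 4T1 alone (mean over the 5 substrates and on each), each coat against uncoated plastic in each condition, an F test over the 5 substrates in each condition, and the difference in T cell effect between each coat and uncoated plastic. A count-based test, edgeR 4.0.16 (quasi-likelihood), was run on the recovered reads as an alternative.

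The replicate number in the labels marks the experiment. Replicates are separate experiments, and the arms with and without T cells are separate wells of an experiment. The number was checked against the values: the correlation of log2 residuals from the group means had a median of 0.478 over 156 pairs of libraries that share a number, and −0.13 over 562 pairs that do not. The closest library carried the same number for 37 of 40 libraries. A model with the experiment as a block was therefore run as an alternative, and its value is given beside each result whose call or count it changes. The block takes out a shift that the arms of an experiment share, but not a T cell effect that differs between experiments. The label descriptions also hold a library tag (none, R2 or R3) whose meaning is not stated. It is not balanced over the arms: in experiment 4 all 5 libraries of 4T1 alone carry R3, while 4 co-cultures carry none and 1 carries R2.

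Gene lists, 37 in number, were fixed before the data were examined, as were the comparisons, the tests, the rule for naming genes and most alternatives. Of these lists, 30 had 5 or more tested members, and 2 members were looked up under an older symbol. Each list was tested with camera at a preset correlation of 0.01, which compares its members with all other genes, and with an estimated correlation as the alternative. Members passing were counted after adjustment over all genes and again adjusted over the list alone. A T cell identity score was the mean log2(value + 1) of the 25 tested genes of that list. Coats were compared on it with a two-sided exact permutation test, and other scores were formed in the same way.

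Genes are named by a rule: an adjusted p under 0.05 and a mean of 5 per M or more in the higher arm. Predicted or unnamed genes and variable, diversity or joining segments of antigen receptors were counted but not named. For T cells added, the rule takes the 10 highest and 10 lowest differences, the 10 highest among genes with a mean of 10 per M or more over the 22 libraries of 4T1 alone, and the 2 members of each list with the smallest adjusted p. On single substrates it adds no name. For each coat and each difference in T cell effect it takes the 5 highest, the 5 lowest and 1 member per list, and for F tests the 5 smallest p. Where fewer than 3 genes pass, the 3 smallest p are named and said not to have passed. The same rule was applied to the model with the experiment block. Positions are from the GENCODE vM21 annotation on mm10, matched by symbol for 180 of 182 named genes.

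Alternatives were other pseudocounts (0.25 and 4), no filter or a filter of 5 per M, quantile normalisation, median-ratio size factors, scaling to the carcinoma epithelial markers, the experiment block with and without the library tag, array weights, edgeR, a minimum log2 difference of 1, fits restricted to the groups compared, and leaving out each experiment or each library. Fits to the libraries of 1 condition, leaving out experiment 4 with the block, and leaving it out for gene lists were added after the data had been seen. The tests were tested on simulated data with 50 genes changed at each fold: for collagen I against uncoated plastic, limma called 12% of genes changed 1.25-fold, 70% at 1.5-fold, 92% at 2-fold and 100% at 4-fold, with 1 unchanged gene called. With the experiment block these shares were 54%, 88%, 94% and 100%, with 9 unchanged genes called. The simulated libraries do not carry the spread in T cell RNA that the co-cultures show.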

Results

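The study asked how extracellular matrix proteins under carcinoma cells bear on their clearance by T cells. RNA of 4T1 cells was measured on uncoated polystyrene (5 libraries alone, 4 with T cells), collagen I (4 and 3), collagen IV (4 and 4), fibronectin (5 and 4) and vitronectin (4 and 3). Experiment 1 holds wells on uncoated plastic and fibronectin only, and the 1 co-culture of experiment 3 was on collagen IV. Comparisons of substrates that are not paired by experiment therefore also reflect which experiments each substrate holds. Depth was 18.95 to 47.73 M (mega) reads per library, except for 239.13 M in collagen IV co-culture replicate 5. The first principal component held 68.1% of the variance and had a correlation of 0.980 with the T cell identity score over the libraries. The second held 13.1%, of which 94.7% lay between experiments.

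Transcripts of T cells were detected in each of the 18 co-cultures, and their amount differed between experiments. The T cell identity score was 0.344 ± 0.031 (SD, n = 22) in 4T1 alone, with a range of 0.290 to 0.416, and 2.87 ± 2.09 (SD, n = 18) in co-culture, with a range of 1.03 to 7.10. It was higher than in 4T1 alone of the same experiment and substrate in 18 of 18 pairs, by 0.680 to 6.78. Co-cultures averaged 5.88 ± 0.685 (SD, n = 5) in experiment 4, 3.63 ± 0.380 (SD, n = 2) in experiment 1, 1.59 ± 0.161 (SD, n = 5) in experiment 2 and 1.19 ± 0.260 (SD, n = 5) in experiment 5, and the single co-culture of experiment 3 had 1.14. Of the 25 genes in the score, 3 averaged 1 per M (reads per mega-read of scaled library size) or more in 4T1 alone.

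Over all replicates, differences in the score between substrates were smaller than the spread within them, most of which lies between experiments. Co-cultures had 2.87 ± 2.03 (SD, n = 4) on uncoated plastic, 2.68 ± 2.51 (SD, n = 3) on collagen I, 2.71 ± 2.93 (SD, n = 4) on collagen IV, 3.16 ± 1.88 (SD, n = 4) on fibronectin and 2.88 ± 2.48 (SD, n = 3) on vitronectin. Against uncoated plastic the differences were −0.193 for collagen I (exact permutation p = 0.829), −0.163 for collagen IV (0.829), 0.289 for fibronectin (0.714) and 0.008 for vitronectin (1), each with an adjusted p of 1 over the 4 tests, where the smallest p the design allows is 0.0286. Within experiments the differences were −0.032 ± 0.089 (SD, higher in 2 of 3 pairs) for collagen I, 0.52 ± 0.91 (2 of 3) for collagen IV, 0.289 ± 0.337 (3 of 4) for fibronectin and 0.169 ± 0.101 (3 of 3) for vitronectin. Their exact sign-flip p were 1, 0.75, 0.25 and 0.25, where the smallest possible with 3 pairs is 0.25.

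**Figure D1:**
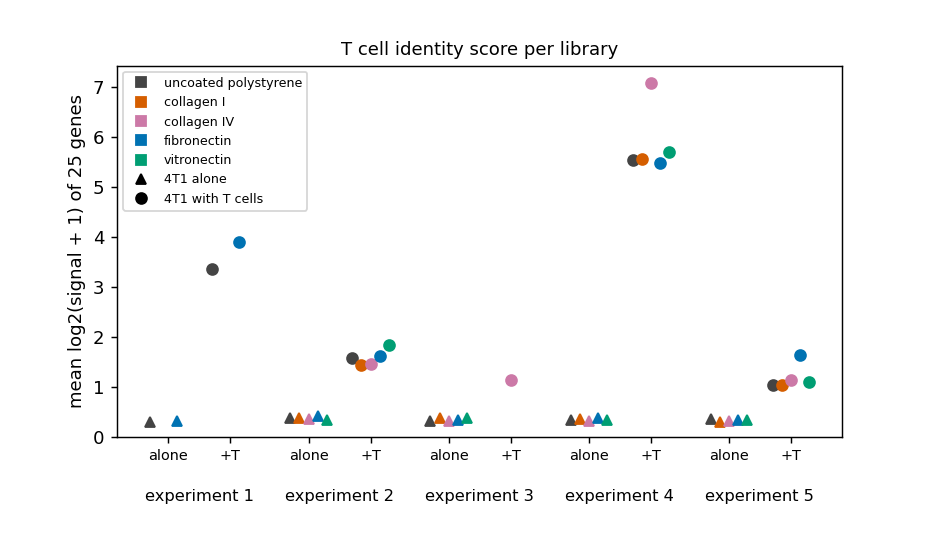
T cell identity score (mean log2(signal + 1) of 25 genes, vertical axis) of each library, by experiment and condition, with a colour per substrate, triangles for 4T1 alone and circles for 4T1 with T cells. The 5 co-cultures of experiment 4 lie between 5.49 and 7.10, and the highest co-culture of the other experiments is at 3.90.

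The largest rises on adding T cells were those of leukocyte and T cell genes. Laptm5, a lysosomal membrane protein of blood cells (chromosome 4, 130913125 to 130936141), averaged 100.3 ± 173.9 per M (SD, n = 18) in co-culture and 0.0708 ± 0.13 (SD, n = 22) in 4T1 alone, a log2 difference of 4.69 ± 0.54 (limma adjusted p = 4.35e-06). The common leukocyte phosphatase gene Ptprc rose by 4.39 ± 0.58 (5.03e-05), the interleukin 7 receptor gene Il7r by 4.13 ± 0.61 (0.000174) and the T cell receptor beta constant gene Trbc2 by 3.73 ± 0.54 (0.000139). Gimap3, Dock2, Grap2 and Rasal3 were also among the 10 highest, and each gene named here was higher in 18 of 18 pairs. Of 14701 genes tested, 3710 passed, 1922 higher and 1788 lower. Without experiment 4, 430 passed (374 higher, 56 lower). Without experiment 3, 1365 passed. Without the co-culture of experiment 4 on vitronectin, collagen I, uncoated plastic or fibronectin alone, 1516, 1885, 2216 and 2335 passed. The library tag differs between the arms of experiment 4, where R3 stands on each library of 4T1 alone and on no co-culture. With the experiment block 6726 passed (3287 higher, 3439 lower), and 1535 with the block and without experiment 4. Neither model allows for a T cell effect that differs between experiments. Wells of an experiment are not independent replicates of that effect, so these counts may be too high.

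The T cell lists rose together. All 25 members of the T cell identity list passed (median 2.47; 25 adjusted over the list alone; camera adjusted p = 1.46e-21, adjusted p = 0.431 with an estimated correlation). Of 14 cytotoxic effector genes, 8 rose and 6 did not pass (median 0.52, 9 adjusted over the list alone, camera adjusted p = 0.000166), among them the granule proteoglycan gene Srgn at 2.17 ± 0.44 and the killer lectin receptor gene Klrd1 at 1.77 ± 0.45. Of 16 T cell activation genes, 12 rose (median 0.63, 12 adjusted over the list alone, camera adjusted p = 4.63e-06), with the interleukin 2 receptor gene Il2rb at 2.48 ± 0.40. Of 8 checkpoint receptors 6 rose (median 0.95, 6 adjusted over the list alone, camera adjusted p = 0.0077). In addition, 5 of 8 regulatory T cell genes rose while 1, Capg, fell (median 0.81, 6 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0145). For these 4 lists, too, the adjusted p was 0.431 with an estimated correlation.

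Interferon gamma response genes rose on adding T cells, by amounts that differed between experiments and did not follow the T cell RNA throughout. Of 22 members, 15 rose and 7 did not pass (median 0.92, 18 adjusted over the list alone, camera adjusted p = 1.69e-07, adjusted p = 0.431 with an estimated correlation). The guanylate-binding protein gene Gbp4 rose by 1.68 ± 0.40 (adjusted p = 0.00724), from 3.25 ± 1.47 (SD, n = 22) to 29.7 ± 57.3 per M (SD, n = 18), and the immunity-related GTPase gene Igtp by 1.66 ± 0.45 (0.0132). Of 19 genes of MHC class I antigen presentation, 5 rose and 14 did not pass (median 0.19, 5 adjusted over the list alone, camera adjusted p = 0.0077, adjusted p = 0.431 with an estimated correlation), including the peptide transporter subunit genes Tap1 (chromosome 17, 34187553 to 34197225) by 1.25 ± 0.32 (0.0104) and Tap2 by 0.56 ± 0.14 (0.0104). Among genes with 10 per M or more in 4T1 alone, the transcription factor gene Tcf7 rose by 1.82 ± 0.44 (0.00767), the thioredoxin-binding protein gene Txnip by 1.67 ± 0.38 (0.00522), the class I transactivator gene Nlrc5 by 0.92 ± 0.29 (0.0235) and the interferon gamma receptor gene Ifngr1 by 0.86 ± 0.23 (0.0121). Each co-culture library also holds RNA of the added T cells, so the rises of the genes in this paragraph cannot be assigned to the carcinoma cells. The interferon gamma score was 4.78 ± 0.897 (SD, n = 5) in the co-cultures of experiment 4 and 2.48 ± 0.186 (SD, n = 5) in 4T1 alone of that experiment, against 2.61 ± 0.133 and 2.30 ± 0.037 (SD, n = 5 each) in experiment 5. Within pairs the rise averaged 2.30 in experiment 4, 0.693 in experiment 1, 0.311 in experiment 5, 0.098 in experiment 2 (4 of 5 pairs) and 0.057 in experiment 3, though the T cell identity score rose more in experiment 2 (1.21) than in experiment 5 (0.863). The score of MHC class I genes rose by 0.698 in experiment 4 and 0.235 in experiment 1, against 0.019, −0.057 and 0.042 in experiments 2, 3 and 5. Of 24 type I interferon response genes, 5 passed and 19 did not (median 0.15, 1 adjusted over the list alone, camera adjusted p = 0.0337, adjusted p = 0.645 with an estimated correlation), and with the experiment block 9 rose, 3 fell and the camera adjusted p was 0.391.

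Genes of the carcinoma cells were lower by small amounts. The growth regulator gene Myc fell by 0.25 ± 0.05 (adjusted p = 0.000833), from 283.1 ± 26.7 (SD, n = 22) to 239.4 ± 29.5 per M (SD, n = 18), and was lower in 18 of 18 pairs. The largest falls were those of Wisp1, a secreted matricellular protein (−0.41 ± 0.14, 0.0324), the cardiac troponin T gene Tnnt2 (−0.39 ± 0.13, 0.0281), Ddah2 (−0.36 ± 0.08, 0.00349) and the adhesion molecule gene Mcam (−0.35 ± 0.11, 0.0194). Of 20 cholesterol biosynthesis genes, 8 fell and 12 did not pass (median −0.11, 11 adjusted over the list alone, camera adjusted p = 0.000166), with mevalonate kinase Mvk at −0.24 ± 0.05 and Mvd at −0.22 ± 0.05, and with the block 16 fell. Of 22 carcinoma epithelial markers, 5 fell and 17 did not pass (median −0.19, 5 adjusted over the list alone, camera adjusted p = 0.000298), with the keratin genes Krt19 at −0.26 ± 0.07 and Krt18 at −0.24 ± 0.07. With the block 15 fell, including the basal keratin gene Krt14 (chromosome 11, 100203162 to 100207548) at −0.41 ± 0.05 (adjusted p = 2.67e-06, and 0.0913 without the block). Both lists had an adjusted p of 0.431 with an estimated correlation. Within pairs the epithelial marker score changed by −0.465 in experiment 4 and by −0.068, −0.113 and −0.091 in experiments 1, 2 and 3. In experiment 5 it did not fall (0.003, higher in 3 of 5 pairs). The cholesterol biosynthesis score was lower in 18 of 18 pairs. It changed by −0.287 in experiment 4, and by −0.174, −0.093, −0.078 and −0.13 in experiments 1, 2, 3 and 5.

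Further lists were lower too. Of 24 ribosomal protein genes 8 fell (median −0.08, 10 adjusted over the list alone, camera adjusted p = 0.000189), of 26 cell cycle genes 8 (−0.10, 11, 0.00139), of 26 focal adhesion and actin genes 6 (−0.11, 2, 0.000451) and of 21 hypoxia and glycolysis genes 8, while 1 rose (−0.17, 11 lower and 1 higher, 0.000749). Of 26 structural matrix genes 2 fell (−0.16, 1, 0.0038), and 14 did with the block. Of 24 matrix remodelling genes 3 fell (−0.13, 2, 0.0151), and 13 did with the block. Each of these 6 lists had an adjusted p of 0.431 with an estimated correlation. Within pairs the cell cycle score changed by −0.224 in experiment 4, and by −0.07, −0.03, 0.004 and 0.013 in experiments 1, 2, 3 and 5. The hypoxia and glycolysis score changed by −0.337, and by −0.026, −0.012, 0.049 and −0.017. Focal adhesion, structural matrix and remodelling scores also fell most in experiment 4 (0.254, 0.421 and 0.299), the ribosomal protein score in experiment 3 (0.223). Of the 20 lists that passed, 11 still did without experiment 4. Scaling each library to the carcinoma epithelial markers moved the median of all genes from −0.01 to 0.16, and the median of the 1788 lower genes from −0.149 to 0.036, so that 0 of them then passed as lower. By quantile normalisation (median of all genes −0.06), 10 of the 20 lists that passed no longer did. None of the 20 lists passed in the opposite direction, relative to all genes, under either of these scalings. A change of direction without passing was not counted. Camera compares a list with all other genes, and the marker scaling shifts all genes nearly alike, so a reversal could hardly arise from it.

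Some transcripts of other blood cells were higher in the co-cultures of experiment 4, where T cell RNA was highest. Ighm, the heavy chain of immunoglobulin M, averaged 63.9 per M in the co-cultures of experiment 4, 3.14 in the other co-cultures and 0.0117 in 4T1 alone. The haemoglobin gene Hbb-bs averaged 5.48, 0.0164 and 0.00461 per M in the same libraries, and the erythroid gene Alas2 0.308, 0.262 and 0.258. The erythroid and platelet score rose by 2.12 within pairs in experiment 4. It rose by 0.184 in experiment 1, where the T cell identity score rose by 3.32, and by 0.046, 0.159 and 0.006 in experiments 2, 3 and 5. Of 5 erythroid and platelet genes, 1 rose and 4 did not pass (median 0.67, 5 adjusted over the list alone, camera adjusted p = 0.00874, adjusted p = 0.431 with an estimated correlation), and without experiment 4 the camera adjusted p was 0.213. Of 5 macrophage genes 2 rose (median 0.11, 2 adjusted over the list alone, camera adjusted p = 0.0325, adjusted p = 0.431 with an estimated correlation), and the macrophage gene Cd68 averaged 3.17, 3.39 and 3.05 per M in the same 3 sets of libraries.

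On single substrates the T cell effect passed for 0 genes by limma on each of the 5. At an unadjusted p under 0.05 there were 1516 genes on uncoated plastic, 159 on collagen I, 1444 on collagen IV, 353 on fibronectin and 1409 on vitronectin, and edgeR called 108, 0, 256, 114 and 0. The unadjusted counts on collagen I and fibronectin are below 0.05 of the 14701 genes tested, the share that chance alone would give. The model with the block called 555 genes on uncoated plastic (153 higher, 402 lower), 1 on collagen IV and 0 on the others. By edgeR with the block there were 1267 on uncoated plastic (682 higher, 585 lower), 329 on collagen I, 1031 on collagen IV, 459 on fibronectin and 852 on vitronectin. The excess of lower genes on uncoated plastic thus turns with the tool, and with the block and without experiment 4 limma gave 259 higher and 114 lower. Without the block, leaving out experiment 4 gave 23 on uncoated plastic and 176 on fibronectin, and leaving out replicate 1 of uncoated plastic gave 14 without its co-culture and 1 without its library of 4T1 alone. Medians of the interferon gamma response list were 0.79 on uncoated plastic (camera adjusted p = 0.00043, adjusted p = 0.621 with an estimated correlation), 1.11 on collagen I (2.23e-14, and 0.33), 1.13 on collagen IV (8.04e-05, and 0.506), 0.89 on fibronectin (5.57e-09, and 0.384) and 0.76 on vitronectin (0.00707, and 0.704). Experiment 4 gave 1 of 3 co-cultures on collagen I and vitronectin and 1 of 4 on the others, so these medians cannot be ranked as differences between substrates.

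**Figure D2:**
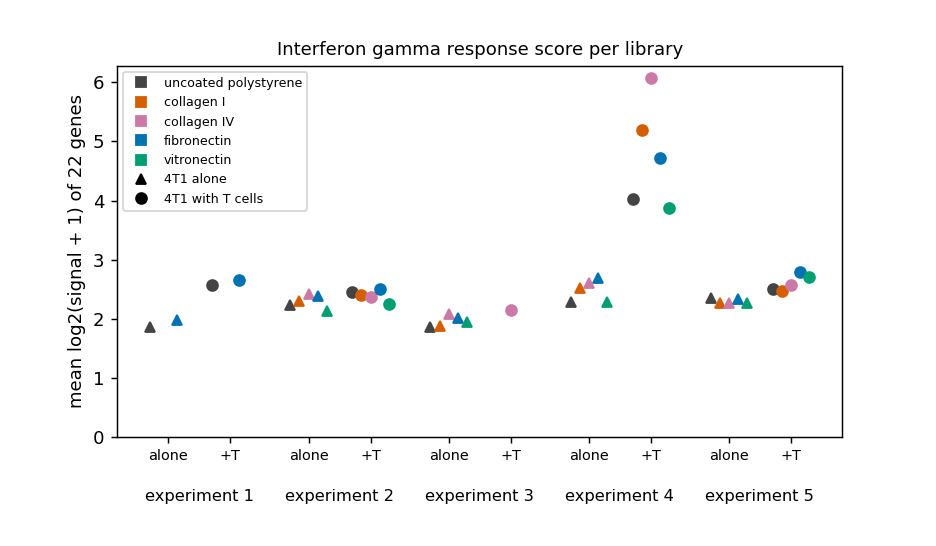
Interferon gamma response score (mean log2(signal + 1) of 22 genes, vertical axis) of each library, by experiment and condition, with a colour per substrate, triangles for 4T1 alone and circles for 4T1 with T cells. The co-cultures of experiment 4 range from 3.88 on vitronectin to 6.08 on collagen IV.

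Collagen I changed expression in 4T1 cells without T cells. The RNA helicase gene Ddx41 (chromosome 13, 55530410 to 55536658) averaged 57.4 ± 2.52 per M (SD, n = 4) on collagen I and 41.6 ± 3.01 (SD, n = 5) on uncoated plastic, a rise of 0.46 ± 0.06 (limma adjusted p = 0.000546). The metalloproteinase inhibitor gene Timp2 (chromosome 11, 118301069 to 118355740) rose by 0.45 ± 0.08 (0.0109), from 357.5 ± 12.2 to 487.4 ± 24.1 per M. So did the sialyltransferase gene St3gal4 (chromosome 9, 35046576 to 35119268) by 0.48 ± 0.09 (0.0109). Vgll4, a cofactor of TEAD transcription factors, rose by 0.59 ± 0.12 (0.038), the diacylglycerol kinase gene Dgkh by 0.53 ± 0.09 (0.00813), the GTPase gene Rab31 by 0.47 ± 0.10 (0.038) and the NF-kB inhibitor gene Tnfaip3 by 0.25 ± 0.05 (0.038). Each of the 7 was higher in 4 of 4 pairs. In all, 14 genes rose and 0 fell.

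The experiment block raised that count to 100 genes, 69 higher and 31 lower, and a fit to the 22 libraries of 4T1 alone with the block to 461 (272 higher, 189 lower). The matrix metalloproteinase gene Mmp14 then rose by 0.52 ± 0.09 (adjusted p = 0.0026, and 0.0672 without the block), with Scarf2 at 0.65 ± 0.14 and Nbl1 at 0.58 ± 0.09. Fgfbp1, Clu, Wisp1 and Il18rap fell by 0.79, 0.66, 0.64 and 0.58. Cholesterol biosynthesis was the list with the smallest p: 0 of 20 members passed (median −0.28, 3 lower adjusted over the list alone, camera adjusted p = 1.85e-14, adjusted p = 0.171 with an estimated correlation). With the block 8 fell, 16 adjusted over the list alone, with a camera adjusted p of 2.57e-24 and an adjusted p = 0.0112 with an estimated correlation. Carcinoma epithelial markers had a median of −0.12 (0 of 22 passed, 0 adjusted over the list alone, camera adjusted p = 0.00955, adjusted p = 0.99 with an estimated correlation), and scaling to them moved the median of all genes by 0.13. Leaving out any 1 of the 9 libraries compared gave 1 to 8 genes in place of 14 (1 without collagen I replicate 2 or 5), and 0 passed without experiment 5.

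In co-culture, Ddx41 was again higher on collagen I, at 56.1 ± 4.44 per M (SD, n = 3) against 38.0 ± 2.62 (SD, n = 4), and was the 1 gene that passed (0.55 ± 0.07, limma adjusted p = 0.000196, higher in 3 of 3 pairs). St3gal4 (0.47 ± 0.10) and Timp2 (0.44 ± 0.09) had an adjusted p of 0.139 and did not pass. With the block 45 genes passed (26 higher, 19 lower): St3gal4 (0.00189) and Timp2 (0.00145) did, and Nbl1, Dlk2, Cmtm3 and Vgll4 rose by 0.63, 0.60, 0.53 and 0.51. In a fit to the 18 co-cultures alone with the block 14 passed, and of these genes Ddx41 did (0.0015) while St3gal4 (0.11), Timp2 (0.0601), Nbl1 (0.0593), Dlk2 (0.11), Cmtm3 (0.0536) and Vgll4 (0.0536) did not. Cholesterol biosynthesis again had the smallest p of the lists (median −0.23, 0 of 20 passed, 2 lower adjusted over the list alone, camera adjusted p = 9.15e-14, adjusted p = 0.205 with an estimated correlation). With the block 6 fell, 14 adjusted over the list alone, with an adjusted p = 0.011 with an estimated correlation. The score of the list was lower on collagen I than on uncoated plastic in 4 of 4 pairs of 4T1 alone (−0.254 ± 0.102, SD) and 3 of 3 of co-cultures (−0.269 ± 0.11, SD). Type I interferon response genes had a median of 0.37 (0 of 24 passed, camera adjusted p = 7.19e-07, adjusted p = 0.832 with an estimated correlation). Interferon gamma response genes had one of 0.49 (0 of 22, 0.00147, and 0.858), which with the block had a camera adjusted p of 0.0516 and with the block and without experiment 4 reversed direction (0.0476). Scaling to the epithelial markers moved the median of all genes by 0.16. Without experiment 4, 2 genes passed, and Ddx41 was not among them.

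Without the block, Nptx1 passed as lower on collagen IV in both conditions and Mmp3 in co-culture only. The neuronal pentraxin gene Nptx1 (chromosome 11, 119538719 to 119547753) averaged 17.5 ± 4.5 per M (SD, n = 4) in 4T1 alone against 55.6 ± 11.8 (SD, n = 5) on uncoated plastic. The log2 difference was −1.62 ± 0.28 (limma adjusted p = 0.0228). In co-culture it averaged 17.0 ± 5.06 against 53.7 ± 14.1 (SD, n = 4 each), with a difference of −1.61 ± 0.29 (limma adjusted p = 0.0486). The stromelysin gene Mmp3 (chromosome 9, 7445822 to 7455975), a secreted matrix protease, fell by 1.79 ± 0.33 (0.0486) in co-culture, from 41.7 ± 14.5 to 11.7 ± 5.28 per M (SD, n = 4 each), and had −1.58 ± 0.32 in 4T1 alone, which did not pass (0.0896). Lower values of these genes were not confined to collagen IV, though neither passed on collagen I or fibronectin in 4T1 alone. On uncoated plastic 4T1 alone had 36.48 to 68 per M of Nptx1 and 30.03 to 51.15 of Mmp3. Fibronectin had 21.9 to 38.48 and 19.3 to 29.42, and collagen I 32.16 to 46.78 and 21.03 to 29.49. Vitronectin had 36.58 to 84.97 and 22.18 to 79.39. Cdh17, a cadherin gene, had −0.73 ± 0.14 in 4T1 alone (0.0549) and Glis3 −0.58 ± 0.13 in co-culture (0.134), neither of which passed. With the block Mmp3 (limma adjusted p = 0.00785) and Cdh17 (0.0018) passed in 4T1 alone, and Glis3 (0.0207) in co-culture. In fits to 1 condition with the block, Mmp3 (0.00641) and Cdh17 (0.00115) passed in 4T1 alone, while Glis3 (0.21) did not in co-culture. By edgeR 2 genes passed in 4T1 alone and 0 in co-culture, where 490 genes had an unadjusted limma p under 0.05 and Nptx1 and Mmp3 had edgeR adjusted p of 0.0654 and 0.0755.

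With the experiment block, 20 genes passed on collagen IV in 4T1 alone (5 higher, 15 lower; 210 in a fit to 4T1 alone with the block, 53 higher and 157 lower) and 42 in co-culture (3 higher, 39 lower). In 4T1 alone the protease inhibitor gene Serpine2 fell by 0.81 ± 0.12 (adjusted p = 0.000493) and the laminin gene Lama3 by 0.71 ± 0.11 (0.00182), and the myelin protein gene Pmp22 rose by 0.68 ± 0.10 (0.000493). In co-culture Mmp10, Lama3, the growth factor gene Areg and the collagen receptor gene Itga2 fell by 1.21, 0.86, 0.81 and 0.53. In a fit to the co-cultures alone with the block 3 genes passed, among them Lama3 (0.0395), while Nptx1 (0.113), Mmp3 (0.178), Mmp10 (0.21), Areg (0.194) and Itga2 (0.178) did not. Matrix remodelling genes in co-culture had 1 of 24 lower (median −0.18, 3 adjusted over the list alone, camera adjusted p = 8.75e-10, adjusted p = 0.0749 with an estimated correlation), and integrins 0 of 14 (median −0.18, 0 adjusted over the list alone, 1.15e-06, and 0.0692). In 4T1 alone the medians were −0.08 (0 of 24 passed, 2 adjusted over the list alone, 0.0108, adjusted p = 1 with an estimated correlation) and −0.15 (0 of 14, 0, 0.000428, and 0.402). Type I interferon response genes had 0 of 24 passing in both conditions, with medians of 0.32 in 4T1 alone (camera adjusted p = 2.39e-09, adjusted p = 1 with an estimated correlation) and 0.31 in co-culture (1.54e-05, and 0.783). Scaling to the epithelial markers moved the median of all genes by 0.22 in co-culture and 0.10 in 4T1 alone. The count in 4T1 alone was 0 without collagen IV replicate 2, 3 or 4 or uncoated replicate 1, 4 or 5, and 2 without uncoated replicate 2. The co-culture count was 0 without collagen IV replicate 3, 4 or 5 or uncoated replicate 1, 4 or 5, and 13 without collagen IV replicate 2.

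**Figure D3:**
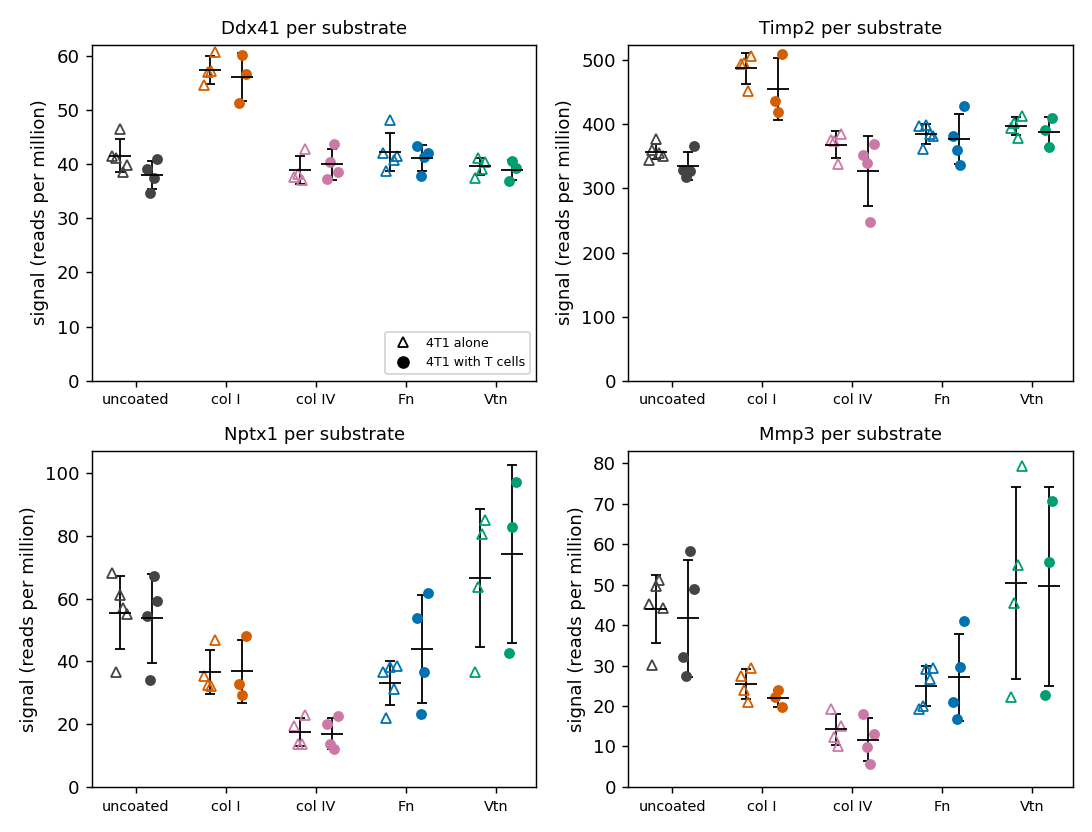
Signal in reads per M (vertical axes, from 0) of Ddx41, Timp2, Nptx1 and Mmp3 on each substrate, with open triangles for libraries of 4T1 alone, filled circles for co-cultures, and lines for the mean ± SD. Ddx41 lies between 51.40 and 60.81 on collagen I, and Nptx1 between 11.91 and 23.02 on collagen IV.

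On fibronectin 0 genes passed by limma in either condition, with 325 (4T1 alone) and 109 (co-culture) at an unadjusted p under 0.05 and 0 and 0 by edgeR. Both unadjusted counts are below the share of genes that chance alone would give. With the block 1 passed in 4T1 alone, and 129 (49 higher, 80 lower) in a fit to the 22 libraries of 4T1 alone with the block. Cdh17 had the smallest p in 4T1 alone (−0.61 ± 0.13, adjusted p = 0.625), and with the block it passed (0.0365) and was lower in 5 of 5 pairs. In co-culture the 3 genes with the smallest p, Mtg1, Ech1 and Ccdc114, had an adjusted p of 1. Cholesterol biosynthesis genes had medians of 0.10 in 4T1 alone (0 of 20 passed, 0 adjusted over the list alone, camera adjusted p = 0.00015, adjusted p = 0.997 with an estimated correlation) and 0.09 in co-culture (0 of 20, 0, 0.00148, and 0.963). Ribosomal protein genes in co-culture had a median of 0.08 (0 of 24, 0, 2.13e-09, and 0.947).

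On vitronectin, too, 0 genes passed by limma, with 164 and 115 at an unadjusted p under 0.05 and 0 and 0 by edgeR. Both unadjusted counts are again below the share that chance alone would give. With the block 2 genes passed in each condition. P-selectin, Selp (chromosome 1, 164115264 to 164150026), an adhesion receptor of platelets and endothelium, rose by 1.02 ± 0.18 (adjusted p = 0.0196, higher in 4 of 4 pairs) in 4T1 alone and by 1.16 ± 0.20 (0.019, 3 of 3 pairs) in co-culture. The adhesion receptor gene Adgrg3 (chromosome 8, 95017692 to 95045250) rose by 0.88 ± 0.15 (0.0196) and by 1.01 ± 0.17 (0.019). Without the block both had an adjusted p of 1 in both conditions. In fits to 1 condition with the block neither passed, with 0.054 for Selp and 0.0695 for Adgrg3 in 4T1 alone and 0.379 for both in co-culture. Cholesterol biosynthesis genes in co-culture had a median of 0.20 (0 of 20 passed, 0 adjusted over the list alone, camera adjusted p = 2.18e-10, adjusted p = 0.515 with an estimated correlation), and the score was higher on vitronectin in 3 of 3 pairs.

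Across all 5 substrates, Ddx41 and St3gal4 differed most by the F test, in 4T1 alone (adjusted p = 7.51e-05 for both) and in co-culture (0.00098 for both). In 4T1 alone 37 genes passed, with Nsmf (0.0013), Cdh17 (0.00178) and Nptx1 (0.00704) next, and in co-culture 19, with Atp2c2, Nptx1 and Npnt, a matrix ligand of an integrin (0.00802 each). With the block the counts were 395 and 235. Fits to the libraries of 1 condition gave 97 in 4T1 alone and 0 in co-culture, and 1444 and 53 with the block. In co-culture 18 of 100 random splits called as many as the 19. Without experiment 5 both were 0, and leaving out single libraries gave 11 to 43 in 4T1 alone (11 without collagen I replicate 4 or 5) and 3 to 27 in co-culture (3 without collagen IV replicate 3).

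The T cell effect differed between coated and uncoated plastic for 0 genes by limma on any coat. At an unadjusted p under 0.05 there were 125 genes for collagen I, 184 for collagen IV, 106 for fibronectin and 41 for vitronectin, and 53 by the F test. By edgeR 0 also passed, with 122, 185, 101, 50 and 49 at an unadjusted p under 0.05. All these counts are below 0.05 of the 14701 genes tested, the share that chance alone would give. Differences between experiments stay in the spread of these models, so 0 genes passing does not show that the T cell effect was equal. The smallest p were those of Dgkh for collagen I (−0.48 ± 0.13), Sirt5 for collagen IV (0.36 ± 0.11), Cope for fibronectin (0.24 ± 0.08) and Ahnak2 for vitronectin (−0.64 ± 0.28), each with an adjusted p of 1. The interferon gamma response list passed camera on each substrate, though not with an estimated correlation (adjusted p of 0.33 to 0.704) and with 0 genes called there, and its differences between a coat and uncoated plastic did not pass. Ribosomal protein genes differed for collagen I (median 0.07, camera adjusted p = 0.0014) and fibronectin (0.07, 0.000578), matrix remodelling genes for collagen IV (−0.16, 0.0202) and cholesterol biosynthesis genes for vitronectin (0.10, 0.00849). Without experiment 4 the camera adjusted p was 0.503, 0.0134, 0.977 and 0.000749. With an estimated correlation their adjusted p was 0.975, 0.943, 0.937 and 0.997, and no member of these lists passed on its own. With the block 4 lists passed camera for collagen IV and 3 for vitronectin, against 1 each without it.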

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

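The tests of explanations in this part were chosen after the results were seen; the comparisons of T cell effect between substrates were fixed before the data were examined. A gap between the highest or lowest library and its nearest neighbour, divided by the range of the group, was computed in 67 groups of 4 or 5 libraries. It was above the 95% critical value (0.83 for 4 libraries, by simulation) in 8, each of 4 libraries. Chance flags about 1 in 20 groups, which makes 3.4 of these 67.

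The T cell identity score of collagen IV co-culture replicate 4 (7.10, next 1.46) lay far from the others of its group, with a gap ratio of 0.947, and all 5 co-cultures of experiment 4 were above those of the other experiments. Depth is argued against as the cause, since 0 of the 5 lay outside the range of the 13 other co-cultures in sequencing depth. The library tag is argued against as well, since the highest co-culture of another experiment with a tag found in experiment 4 had 3.895, below the lowest of experiment 4 (5.487) by more than the SD of its co-cultures (0.685). The haemoglobin and immunoglobulin M transcripts that came with these libraries leave the composition of the added cells open, and no biological explanation was tested. How many T cells were seeded, survived or were recovered in experiment 4 cannot be read from these values.

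Genes lower in co-culture were many (1788) and their falls small. Dilution by T cell RNA stays open: after scaling to the carcinoma epithelial markers the median of these genes was 0.036 (SD 0.057) in place of −0.149, but that scaling shifts all genes alike (median −0.01 to 0.162), so the loss of calls follows from the shift. The submitters' scaling stays open: with median-ratio size factors 1354 genes were still lower, but these factors (0.981 to 1.011) nearly repeat that scaling and so do not test it. In the model with the experiment block, 90 of 3439 lower genes stayed lower after the marker scaling and 276 passed as higher; 3 of the 90 are themselves markers used for the scaling. A fall in the carcinoma cells themselves, beyond the markers used for scaling, stays open.

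The interferon gamma response score of experiment 4 stood apart in the 3 co-culture groups large enough for the gap ratio: uncoated plastic (4.03, next 2.57, gap ratio 0.924), collagen IV (6.08, next 2.57, 0.892) and fibronectin (4.73, next 2.78, 0.873), and was also highest on collagen I (5.19, next 2.47) and vitronectin (3.88, next 2.71). The share of T cell RNA is argued against as the cause of the spread within experiment 4 outside collagen IV. Over the 4 other co-cultures T cell identity scores span 0.224 and interferon scores 1.31, where no other experiment exceeds 0.314. Co-cultures of the other experiments held less T cell RNA (scores of 3.895 at most), which makes 0.314 a loose yardstick. The collagen IV co-culture of experiment 4 was left out. It was highest on both scores (7.10 and 6.08), so T cell RNA stays open for it. A difference already present without T cells is argued against as the whole cause, since 4T1 alone of that experiment spans 0.406, but a smaller one that T cells enlarge stays open: vitronectin (2.28) and uncoated plastic (2.29) were lowest there too, below collagen I (2.53), collagen IV (2.61) and fibronectin (2.69). The substrate cannot be told apart from variation between wells, with 1 co-culture per substrate in each experiment and an exact p of 0.972 for a shared order of substrates over experiments 2, 4 and 5. Well-to-well variation in T cell activity stays open and was not tested.

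The other libraries far from their group were these. The cholesterol biosynthesis score of 4T1 alone on collagen I was lowest in replicate 3 (5.44, next 5.58, gap ratio 0.859). Collagen IV co-culture replicate 5 had 239.13 M reads (next 38.08, 0.913). Vitronectin replicate 2 of 4T1 alone had 38.34 M reads (next 25.93, 0.909). The T cell identity score of 4T1 alone on vitronectin was highest in replicate 3 (0.385, next 0.344, 0.854), within the range of 4T1 alone on the other substrates.

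A difference in T cell effect between a coat and uncoated plastic passed camera for 4 lists, and none did with an estimated correlation. With the experiment block 1, 4, 1 and 3 lists passed for collagen I, collagen IV, fibronectin and vitronectin, again none with an estimated correlation. Ribosomal protein genes had a higher T cell effect on collagen I (median 0.07, adjusted p = 0.0014; 0.975 with an estimated correlation) and on fibronectin (0.07, 0.000578; 0.943). Matrix remodelling genes had a lower one on collagen IV (−0.16, 0.0202; 0.937), carried by experiment 4: the T cell effect on the score was −0.62 on collagen IV and −0.126 on uncoated plastic there, −0.045 and −0.084 in experiment 2, and −0.128 and −0.037 in experiment 5. Cholesterol biosynthesis genes had a higher one on vitronectin (0.10, 0.00849; 0.997). Without experiment 4 the camera adjusted p of these 4 was 0.503, 0.0134, 0.977 and 0.000749. The collagen IV co-culture of experiment 4 also had the highest T cell identity score (7.10) and the lowest epithelial marker score (5.68) of the co-cultures.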

How the results depend on the processing

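Fits to the libraries of 1 condition, leaving out experiment 4 together with the experiment block, and leaving out experiment 4 for gene lists were chosen after the data had been seen; the other alternatives were fixed before the data were examined. Over all alternatives, the 4 differences in T cell identity score did not reach an adjusted p under 0.05 in 40 of 40 values. With all libraries the smallest p possible is 0.0286 by exact permutation, and 0.125 (fibronectin) or 0.25 by sign flips. Passing was thus hardly possible, and the 40 of 40 does not measure how far the differences moved. The SDs between replicates were 1.88 to 2.93. Leaving out an experiment changed the sign of the difference for collagen I (−0.749 to 0.016), collagen IV (−0.738 to 0.359) and vitronectin (−0.519 to 0.288). For fibronectin the sign did not change (0.179 to 0.401). Counts of genes stayed within 1.5 times in 551 values and moved in 181. A count of 0 in the main fit that stayed at 0 is among the 551. Of the values of named genes, 1461 kept direction and side of the threshold, 212 no longer passed, 20 newly passed and 13 reversed. Of the values of gene lists, 452 kept both, 362 no longer passed and 2 reversed. Of the 20 lists that passed for T cells added, 0 passed with an estimated correlation, 18 with the experiment block, 10 with quantile normalisation, 14 with scaling to the epithelial markers and 11 without experiment 4. Beside each change below, the cause was not tested.

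With the experiment block, limma called 6726 genes for T cells added (3287 higher, 3439 lower), 555 on uncoated plastic and 1 on collagen IV. For substrates in 4T1 alone it called 395 by the F test, 100 on collagen I, 20 on collagen IV, 1 on fibronectin and 2 on vitronectin. In co-culture these were 235, 45, 42, and 2 on vitronectin. With the block and the library tag it called 842 on uncoated plastic, 46 on collagen I, 5081 on collagen IV and 19 on fibronectin for T cells added. The substrates then gave 604, 178, 57 and, on vitronectin, 3 in 4T1 alone; 585, 75, 63 and 1 in co-culture; and the T cell effect differed for 2 genes on collagen IV.

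By edgeR, T cells added gave 108 genes on uncoated plastic, 256 on collagen IV and 114 on fibronectin, and collagen IV gave 2 in 4T1 alone and 0 in co-culture. With edgeR and the block, T cells added gave 6695 (3292 higher, 3403 lower), and 1267, 329, 1031, 459 and 852 on uncoated plastic, collagen I, collagen IV, fibronectin and vitronectin. The substrates gave 377 by the F test, 97, 20, 1 and 1 in 4T1 alone, and 222, 42, 34 and, on vitronectin, 1 in co-culture. Array weights gave 6 on uncoated plastic, 295 on collagen IV and 193 on fibronectin for T cells added; 283, 66, 52 and, on fibronectin, 5 in 4T1 alone; 303, 9 and 19 in co-culture; and 1 for any difference in T cell effect.

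Scaling to the epithelial markers gave 480 genes for T cells added (480 higher, 0 lower); 15 by the F test, 6 on collagen I and 0 on collagen IV in 4T1 alone; and 8 by the F test and 1 on collagen IV in co-culture. It reversed the log2 difference of T cells added for Mcm7 (0.07), Birc5 (0.059), Itga5 (0.035), Tagln2 (0.069), Ankrd1 (0.026), Timp1 (0.013), Aldoa (0.015), Hspe1 (0.03), Hspa8 (0.081), Rpl15 (0.092), Rplp0 (0.087) and H3f3a (0.097). Quantile normalisation reversed Hspa8 (0.029) and gave 13 by the F test and 5 on collagen I in 4T1 alone and 8 by the F test in co-culture. A minimum log2 difference of 1 left 359 genes for T cells added, 2 and 3 for the F tests in 4T1 alone and co-culture, and 0 and 0 for collagen I, by the construction of the threshold. No filter gave 7 on collagen I in 4T1 alone, and 12 by the F test and 0 on collagen IV in co-culture. A pseudocount of 0.25 gave 4 for T cells added on fibronectin and 2 for collagen IV in 4T1 alone, and one of 4 gave 0 for collagen IV in co-culture.

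Fits to the compared groups alone gave 97 by the F test, 7 on collagen I and 0 on collagen IV in 4T1 alone, and 0, 0 and 0 in co-culture. Fits to the 22 libraries of 4T1 alone gave 97 by the F test and 29 on collagen I, and with the block 1444, 461 (272 higher, 189 lower), 210 (53 and 157) on collagen IV, 129 (49 and 80) on fibronectin and 2 on vitronectin. Fits to the 18 co-cultures gave 0 by the F test, 0 on collagen I and 0 on collagen IV, and with the block 53 by the F test, 14 on collagen I, 3 on collagen IV and 0 on vitronectin (483 at an unadjusted p under 0.05). Of the named genes that passed with the block over all 40 libraries, these fits with the block kept 17 of 17 on collagen I, 9 of 9 on collagen IV, 1 of 1 on fibronectin and 0 of 2 on vitronectin in 4T1 alone, and 4 of 14 on collagen I, 1 of 11 on collagen IV and 0 of 2 on vitronectin in co-culture.

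Leaving out an experiment or a library gave these ranges. T cells added ranged from 430 (without experiment 4) to 5265 (without experiment 2), from 0 to 23 on uncoated plastic and 0 to 176 on fibronectin. In 4T1 alone the F test ranged from 0 to 43, collagen I from 0 to 8 and collagen IV from 0 to 6; in co-culture they ranged from 0 to 27, 1 to 2 and 0 to 16. Single substrates and coats not named here, and differences in T cell effect, stayed at 0 by limma. Without experiment 4 the interferon gamma response list reversed on collagen IV in co-culture (camera adjusted p = 0.0301). Without it and with the block the list reversed on collagen I in co-culture (0.0476). T cells added then gave 1535, and 373, 4, 393 and 2 on uncoated plastic, collagen IV, fibronectin and vitronectin; the substrates gave 497, 256, 7, 6 and 4 in 4T1 alone and 227, 118, 8 and, on vitronectin, 2 in co-culture.

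Depth sets a floor of 3 reads, 0.0124 to 0.158 per M depending on the library, under which a gene listed at 0 is not shown to be absent.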

Other observations

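TGF-beta signalling genes were higher on vitronectin as a group when experiments were in the model, but not without them. The score of the 19 genes was higher on vitronectin than on uncoated plastic in 4 of 4 pairs of 4T1 alone (0.089 ± 0.033, SD) and in 3 of 3 pairs of co-cultures (0.105 ± 0.052, SD). The integrin score was higher in the same pairs (0.09 ± 0.035 and 0.107 ± 0.081, SD). In the model with the block the TGF-beta list had a camera adjusted p of 0.0127 in 4T1 alone (adjusted p = 0.038 with an estimated correlation) and 0.00709 in co-culture (0.0322). Without the block these were 0.31 and 0.124. By the block 0 of 19 members passed in either condition.

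Cd274, the checkpoint ligand PD-L1, which was picked after its values were seen, followed the interferon gamma response in experiment 4. It had 7.49 per M in co-culture on uncoated plastic, 19.9 on collagen I, 48.1 on collagen IV, 11.8 on fibronectin and 6.07 on vitronectin, against 1.82, 2.6, 3.01, 2.57 and 2.21 in 4T1 alone. Among genes of other cell types, Ighm reached 133 per M at most in a co-culture, the B cell gene Cd79a 2.09 and the myeloid gene Lyz2 2.95, against 102 for the T cell gene Cd3e, and the haemoglobin gene Hba-a1 reached 12.

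The tests that follow were chosen after the results were seen. Responses to the coats may be shared by 4T1 alone and the co-cultures. Matching each coat to itself across the conditions, using pairs of libraries from different experiments, gave a mean covariance of 0.00179 over 11125 genes, and −0.0014 for unlike coats. The real matching was the highest of 24 (exact permutation p = 0.0417, the smallest they can give; highest other 0.000897). Of genes called in fits to 4T1 alone with the block, 396 of 461 on collagen I, 182 of 210 on collagen IV, 79 of 129 on fibronectin and 2 of 2 on vitronectin had the same sign in co-culture. These shares of 85.9%, 86.7%, 61.2% and 100% compare with 50.3%, 42.5%, 34.9% and 50% for the other coats.

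A fall in carcinoma cells beyond dilution was tried on genes chosen in experiments 1 to 3 (8 pairs) and read in experiments 4 and 5 (10 pairs), after the marker scaling. Of the 100 lowest genes 44 were again lower, against 9.4% of 11103 genes, and 0 of 10000 random lists reached that share. Their median was nevertheless 0.034, above 0 (all genes 0.212). It was 0.116 in experiment 4 (all genes 0.416) and −0.031 in experiment 5 (all genes 0.008). The first yardstick alone would have favoured the explanation; the second was added after the first result was seen, and together they leave it open.

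Libraries were also regrouped at random into groups of the same sizes. For T cells added, 3710 genes were called and at most 1 in the other splits (1 of 100 as large, and 1 of 100 when swapping within the 18 pairs, highest other 0). A count that large was thus not reached by regrouping single wells. Co-cultures of 1 experiment move together (median correlation of residuals 0.88), while the splits move wells or pairs singly. They therefore do not exclude chance with the experiment as the unit. For substrates in 4T1 alone, the F test called 37 (highest other 3), collagen I 14 (0) and collagen IV 1 (0). Each had 1 of 100 splits as large. Collagen I in co-culture called 1 (highest other 0, 1 of 35). Counts as large were thus rare among splits that ignore the experiments, which by itself does not exclude chance. For collagen IV in 4T1 alone and collagen I in co-culture the count rests on 1 gene. Of splits that part as many pairs of an experiment as the real one, 10 were drawn for each of these coats in 4T1 alone and 7 for collagen I in co-culture, with a highest of 0, which is too few for a share under 0.05. For the F test in co-culture, 18 of 100 splits called 19 genes or more, the highest 4739, and for collagen IV in co-culture 5 of 35 called 2 or more, the highest 3218, so chance cannot be excluded.

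Splits that call many more genes than the real one point to a structure of the samples. The split with 4739 put 3 co-cultures of experiment 4 in a group of 4, so that groups differed in 27.6% of the variance of the T cell identity score, against 0.7% for the real groups. The split with 3218 parted experiments 1, 2 and 3 from experiments 4 and 5. For collagen IV in co-culture, the 7 splits that part as many pairs of an experiment as the real one include none as large, with a highest of 0, and those with more genes part fewer pairs. With the block the counts were 235 and 42.

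For the comparisons with 0 genes by limma every split is as large by construction, so the splits say nothing about these comparisons. For T cells added these were 100 of 100 on uncoated plastic and on fibronectin (highest other 0 each), and 35 of 35 on collagen I (0), collagen IV (690) and vitronectin (0). For coats they were 100 of 100 for fibronectin and vitronectin in 4T1 alone and 35 of 35 in co-culture (highest other 0 each). For the difference in T cell effect they were 100 of 100 throughout, with a highest other of 1855 for the F test, 2 for collagen I, 1895 for collagen IV, 3905 for fibronectin and 1113 for vitronectin.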
